A study of Mus musculus with 4 samples.

How the data were processed

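CTCF ChIP-seq was compared between 1 control library and 1 library labelled CTCF knockout, each from cardiac myocytes of 3 pooled hearts, per the labels' protocols. The 2 input samples have no peak list and were not analysed here as samples of their own. Per the submitters' processing notes, Bowtie2 2.2.6, SAMtools 0.1.19 and MACS2 were used with the mm10 build; the MACS2 version, its threshold, duplicate handling and scaling are not given in the sources used here. Peaks were called per library, and the region names in the deposited lists carry the words input_BG. In the deposited lists each region has a fold enrichment (a ratio over the local background), a −log10 p and a −log10 q, a score and a summit position. The deposited score equalled the whole part of 10 times the −log10 q in all regions, and the lowest −log10 q was 1.32 in the control list and 1.37 in the other, just above 1.30, the value for a q of 0.05. The fold enrichment and −log10 p are the authors' values for each region and were ranked only within their own list; where both lists' values stand side by side no direction is read from them.

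All regions were used as deposited, since no lines overlapped. Regions were counted as shared with an overlap of at least 1 bp. Wilson 95% intervals were computed for shares, and random overlap was taken from 100 placements on the same chromosomes. Gene positions came from a RefSeq gene table of the GRCm38.p6 assembly, the assembly called mm10, restricted to chromosomes 1 to 19, X and Y. That table gives gene starts and ends without strand, exons or sequence. The planned windows around transcription start sites were therefore measured from the gene span (10 kb for gene lists) or from either gene end (1 kb for position classes), and the planned motif search and exon and intron classes were not run. Protein-coding and long non-coding genes were used for position classes. Mitochondrial regions, 12 in the control list (all 12 kept) and 14 in the other, stayed in the region counts. They were classed as lying between genes, since the gene table leaves that chromosome out. Of the 347 listed gene symbols 346 were matched to distinct entries within their list, because Ctgf is an older name of Ccn2. For each of the 15 lists, the share of nearby control regions that were kept was set beside 10000 random gene lists of the same size, matched on control fold enrichment. Under other settings 2000 random lists were used. Clustered genes share regions, which the random lists do less. A random list can thus hold more distinct regions than a clustered list of as many genes. Its range is then too narrow, and the percentile of the clustered list can be too extreme.

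The lists give no depth. If the fold enrichment is (pileup + 1) / (background + 1) and p is the upper Poisson tail, as MACS2 computes them, both can be solved for the pileup and the background. A whole pileup gave the deposited −log10 p within 0.001 for 100% of regions in both lists. Pileups ranged from 6 to 272 reads in the control and from 6 to 274 in the other list. The ratio of the lowest backgrounds, 0.846, was taken as the relative depth; under MACS2's model it is proportional to the number of ChIP reads times the fragment length. It therefore mixes read number with fragment length. Control pileups were thinned binomially by this ratio in 100 draws. Thinning does not repeat peak calling, so it was read at a pileup of at least 15. On simulated data the recovery gave the exact pileup for 100% of 16768 regions. Thinning gave a difference of -0.634% for equal signal and -46.2% for a signal 30% lower, both at a pileup of at least 15. These simulated counts had no background and no peak-calling threshold.

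Named regions followed a rule fixed before the data were examined, except for how distance to a gene was measured. The rule took Ctcf, the 10 strongest lost, the 10 strongest kept and the 5 strongest labelled-knockout-only regions. It also took up to 2 genes with the strongest lost and kept region per list. Regions outside the lists were to be named by the protein-coding gene with the nearest transcription start site within 100 kb. Without strand, the nearest gene span within 100 kb was used instead. A region deep within a long gene could thus be named after it with both gene ends over 100 kb away, as for Itpr1 and Abca13. Some regions that this rule names are not reported here. Other settings fixed before the data were examined were a −log10 q or a fold enrichment of at least 5, a reciprocal overlap of at least 50%, summits within 100 bp, lists of equal length, the strongest 25% of control regions, −log10 p in place of fold enrichment, and other gene windows. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.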

Results

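CTCF, the zinc-finger protein that binds insulators and the borders of chromatin loops, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in cardiac myocytes isolated from the left ventricle of C57BL/6 mice. One library came from control hearts and one from hearts labelled CTCF knockout, each made from a pool of 3 hearts. There was thus 1 ChIP library per genotype and no replicate, so no test between genotypes was possible. Every difference given here compares 2 libraries, and the 95% intervals cover counting error only. The input library of each genotype was not analysed here as a separate file. The lists give no read depth. The lowest local background, shared by 34.0% of control regions and 30.9% of regions in the other list, was 1.01 reads in the control and 0.851 reads in the library labelled knockout. The second value was 0.846 of the first.

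The first question was how many CTCF regions remained in the library in which CTCF itself was the labelled target of the deletion. The control list held 20043 regions covering 5.21 Mb, and the list labelled CTCF knockout held 16128 regions covering 4.14 Mb, which is 0.805 of the control number. Median region width was 228 bp in the control and 225 bp in the other list. The authors' median fold enrichment was 6.98 and 7.13, each relative to the background of its own library. Because the library labelled knockout still held most of the number of regions of the control, it is called by its label throughout. At the Ctcf gene (chromosome 8, 105636474 to 105682922, mm10), both control regions within 10 kb were also called in the library labelled knockout. The region at the gene's lower-coordinate end (105636717 to 105637104) had a fold enrichment of 8.47 in the control list and 5.94 in the other list. The region 3.0 kb beyond the opposite end (105685812 to 105686024) had 4.31 and 7.80. Among regions with a pileup of at least 15 reads, the library labelled knockout held 8054 and the control 10874, a ratio of 0.741. With the control pileups thinned by the ratio of the lowest backgrounds, an alternative added after the data were examined, the control held 8083 such regions on average (range 8004 to 8171 over 100 draws), and the ratio was 0.996.

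**Figure D1:**
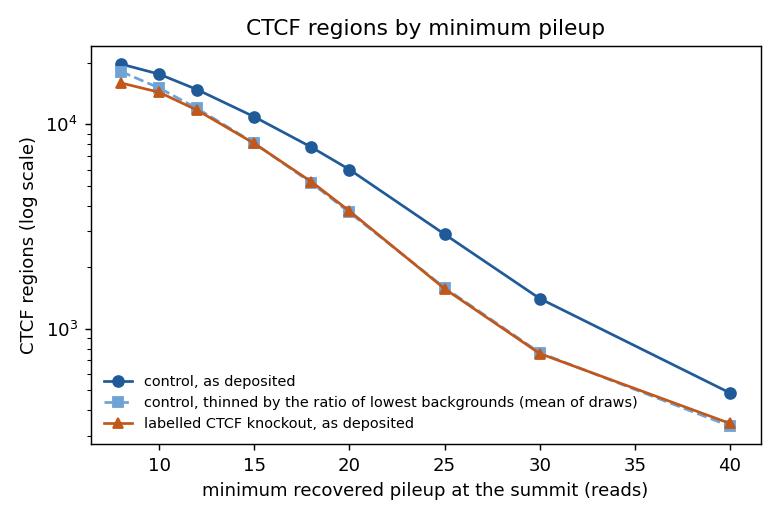
Number of CTCF regions (vertical axis, log scale) whose recovered summit pileup in reads reached the minimum on the horizontal axis, for the control list, the control list thinned by the ratio of the lowest backgrounds and the list labelled CTCF knockout. From a minimum of 15 reads upward the thinned control and the labelled-knockout points lie within 3.02% of each other, while the control as deposited lies above both.

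The 2 lists were then overlapped to ask which regions were called in both libraries. Of the control regions, 13832 (69.0%, Wilson 95% interval 68.4 to 69.6) overlapped a region of the library labelled knockout by at least 1 bp, and these are called kept. The other 6211 control regions (31.0%) are called lost, which says only that no region was called there in the second library. When the labelled-knockout regions were placed at random on the same chromosomes, 0.377% of control regions were overlapped on average and 0.524% at most over 100 placements. In the reverse direction, 2292 labelled-knockout regions (14.2%, interval 13.7 to 14.8) overlapped no control region. Kept control regions were stronger than lost ones, with a median control fold enrichment of 8.14 (interval 8.05 to 8.20) against 5.48. In the weakest of 10 equal bins of control fold enrichment 32.5% were kept (30.5 to 34.6). In the strongest bin 1985 of 2005 regions were kept (98.5 to 99.4%), with 20 regions lost. Within the labelled-knockout list the shared regions had a median fold enrichment of 7.56 and the unshared ones 5.40. The shared percentage depended on the overlap rule, and fell to 59.8% with a reciprocal overlap of at least 50%.

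**Figure D2:**
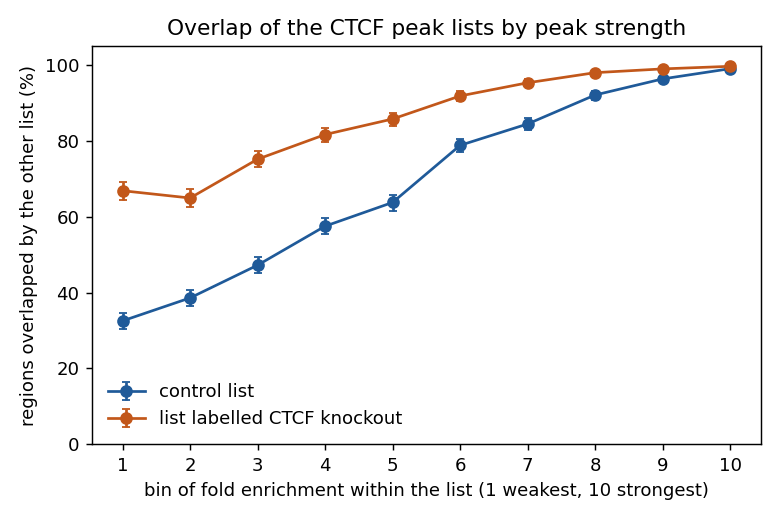
Percentage of regions overlapped by the other list (vertical axis) in 10 equal bins of fold enrichment within each list (horizontal axis), with Wilson 95% intervals as bars. The control list runs from 32.5% in its weakest bin to 1985 of 2005 regions in its strongest, and the list labelled knockout from 66.8% to 99.6%.

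Of the 10 strongest kept regions, 7 lay within 1 kb of a gene end, where 21.8% of all control regions lay. These 10 were also the strongest of the whole control list, since no lost region had a fold enrichment above 15.2. Ranked by control fold enrichment, the first was on chromosome 18 (34776557 to 34777528) beside Kdm3b, a histone H3 lysine 9 demethylase gene, with a fold enrichment of 41.4 in the control list and 36.7 in the other. The next were beside Nsfl1c (chromosome 2, 151494022 to 151494366; 40.8 and 21.0) and Adprhl2 (chromosome 4, 126321500 to 126321980; 36.8 and 25.1). Regions near Rfx7, Vps36, Pkn3, Rapgef1 and Nipsnap2 were also among the 10, with control fold enrichments from 35.5 down to 30.2. The strongest lost regions were weaker than these. The first lay within Wnt5a, a secreted Wnt ligand gene (chromosome 14, 28507532 to 28507821), with a control fold enrichment of 15.2 and a recovered pileup of 31 reads. Those within Mtarc2 (chromosome 1, 184824583 to 184824884) and 7.46 kb from Wfdc21 (chromosome 11, 83739364 to 83739611) had 13.96 and 13.38. Lost regions near Enc1, Dpf3 (a chromatin remodelling subunit gene), Mgst3, Rsph14 and Urad, and within Itpr1 (an intracellular calcium release channel gene) and Map3k5, had control fold enrichments between 13.2 and 12.7. Those named after Dpf3, Mgst3 and Rsph14 lay 14.7, 21.2 and 36.4 kb from these genes. Among regions called only in the library labelled knockout, the strongest lay within Abca13 (chromosome 11, 9317407 to 9317589), with a fold enrichment of 12.4 in that list. Regions near Igfn1, near Has2 (a hyaluronan synthase gene) and at an end of Rnf150, and a region on chromosome Y (9647251 to 9647403) with no protein-coding gene within 100 kb, each had 11.9.

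Gene lists fixed before the data were examined were used to ask whether regions near genes of heart muscle were kept as often as regions near other genes. Near sarcomere genes (within 10 kb of the gene), 25 of 37 control regions were kept (67.6%, interval 51.5 to 80.4). Matched random lists gave a median of 68.0%. Under other settings this list stayed inside the central 95% of random lists. Its percentile ran from 11.8 with a window of 50 kb (68.5% kept, random median 74.1%) to 94.5 with a −log10 q of at least 5 (87.5% kept, random median 76.0%). Regions beside Mybpc3 (myosin-binding protein C) and Tnni3 (cardiac troponin I) were the strongest kept ones, with control fold enrichments of 19.3 and 15.1, and regions within Actn2 (8.0) and Ttn (6.48) were the strongest lost ones. Near genes of calcium handling and ion channels 29 of 41 regions were kept (70.7%). Kcnq1, a potassium channel gene, had both a kept region (13.1) and a lost one (7.71). A region 9.34 kb from Kcnh2 (14.96) was kept and one within Camk2d (8.63) was lost. Near genes of fatty acid and energy metabolism 20 of 24 regions were kept (83.3%), including regions near Slc27a1 (18.99) and Slc2a4, the insulin-responsive glucose transporter gene (14.96), while a region near Hadha (7.85) was lost. Near stress and fetal genes 10 of 17 were kept (58.8%), with kept regions near Gadd45b (14.6) and Ccn2 (12.2) and lost ones near Jun (8.47) and Xirp1 (7.98). Near cardiac transcription factor genes 21 of 38 were kept (55.3%, interval 39.7 to 69.9), at percentile 2.68 of the random lists, whose median was 70.4%. Kept regions there included those near Tbx2 (13.5) and Esrra (13.0), and lost ones those near Hand2 (10.97) and Tbx3 (9.06). For calcium handling and ion channels the random median was 70.3%, for fatty acid and energy metabolism 73.1%, and for stress and fetal genes 71.4%. A gene named here for a lost region can also have kept ones. Kept were 1 of 3 control regions near Ttn, 2 of 3 near Xirp1 and 1 of 4 near Tbx3. Near Camk2d and near Hadha 1 of 2 was kept, while none was kept near Actn2, Jun or Hand2.

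The same count was made for genes of chromatin architecture, clustered gene families and other cell types. Near genes of CTCF and cohesin 19 of 28 regions were kept (67.9%), with a kept region at Esco1, a cohesin acetyltransferase gene (21.8), and a lost one beside Smc3, a cohesin subunit gene (10.6). At imprinted genes 22 of 32 were kept (68.8%), among them regions near Cdkn1c (13.7) and Ddc (8.97), and regions at Commd1 and Copg2 (6.33 each) were lost. In the Hox clusters 13 of 21 were kept (61.9%, interval 40.9 to 79.2, percentile 3.37). This interval covers the random median of 72.2%. Kept regions included those at Hoxd3 (13.5) and 1.31 kb from Hoxa9 (11.2), and regions near Hoxd13 (7.98) and Hoxd11 (6.98) were lost. In the protocadherin clusters 8 of 15 were kept (53.3%, interval 30.1 to 75.2), where Pcdhgb6 had a kept region (9.49) and Pcdhga12 a lost one (6.48). At loci known from textbooks for CTCF binding 11 of 19 were kept (57.9%), including a region near Epha4 (13.7), and a region at Myc (6.82) was lost. Of the genes named here for a lost region, Commd1 kept 2 of 4 regions and Pcdhga12 2 of 5. Myc and Smc3 each kept 1 of 3, and none was kept near Copg2, Hoxd13 or Hoxd11. Near housekeeping genes 10 of 17 were kept (58.8%, percentile 5.42), where the random lists had a median of 73.7%, so that the gap to the random median was -14.9 points there and -15.1 points for the cardiac transcription factors. Among markers of other cell types in heart tissue, 13 of 17 regions near fibroblast genes, 13 of 19 near endothelial genes, 7 of 7 near immune genes and 11 of 14 near smooth muscle and pericyte genes were kept. The strongest were at Col1a1 (22.4), 6.95 kb from Eng (16.2), at Spi1 (19.3) and at Myh11 (12.2). The Spi1 region is the same one as the Mybpc3 region. None of the 15 lists lay outside the central 95% of 10000 random gene lists matched on control fold enrichment, where chance would place 0.75 of a list. That chance number is approximate, since the immune markers, with 7 of 7 kept, could not go above percentile 94.98. The cardiac transcription factors, at percentile 2.68, lay close to the limit of 2.5. With other settings 1 to 3 lists lay outside, most often the cardiac transcription factors.

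**Figure D3:**
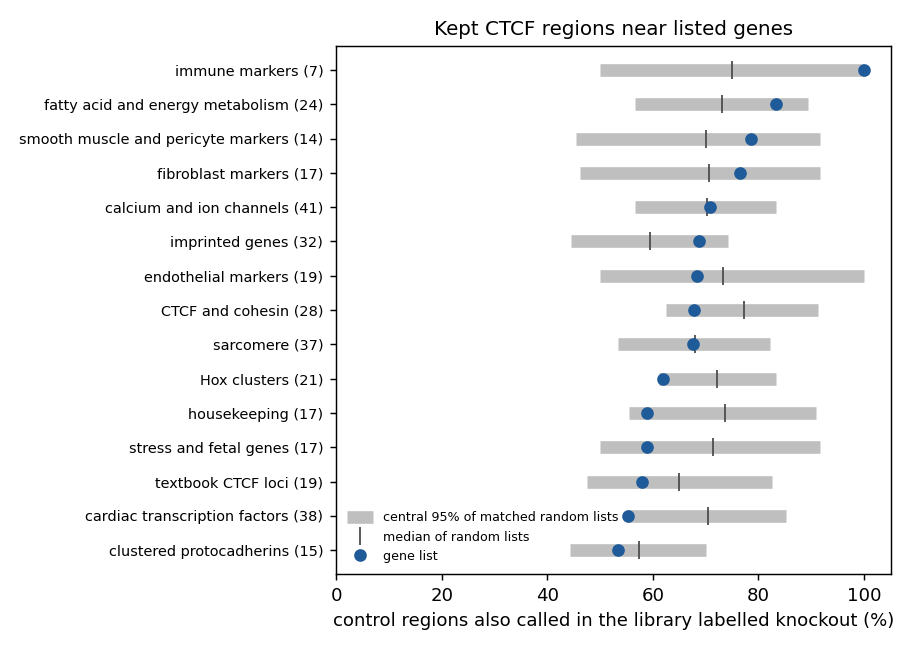
Percentage of control CTCF regions near each gene list that were also called in the library labelled knockout (points; number of regions in brackets), with the central 95% range (grey bars) and the median (ticks) of matched random lists. Every point lies inside its grey range, from 53.3% for the protocadherin clusters to 100% for the immune markers.

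Regions were also compared by their position relative to genes. Within 1 kb of either end of a gene, 2860 of 4375 control regions were kept (65.4%, interval 63.9 to 66.8). In gene bodies 6116 of 8986 were kept (68.1%), and between genes 4856 of 6682 (72.7%, interval 71.6 to 73.7). The share at gene ends minus that between genes was -7.30 percentage points (interval -9.07 to -5.53). At the same control fold enrichment the difference was -7.54 points. The median control fold enrichment was 7.30 at gene ends and 7.07 between genes. Gene ends held 21.8% of the control list and 19.9% of the list labelled knockout. The difference kept its direction but was -3.00 points with a −log10 q of at least 5, -3.34 with a fold enrichment of at least 5 and -2.51 with a window of 5 kb around gene ends, or -5.83, -5.15 and -3.77 at the same control fold enrichment. The order of gene ends and gene bodies turned with the −log10 q threshold (71.1% and 69.98%) and with the window of 5 kb (68.8% and 67.5%).

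**Figure D4:**
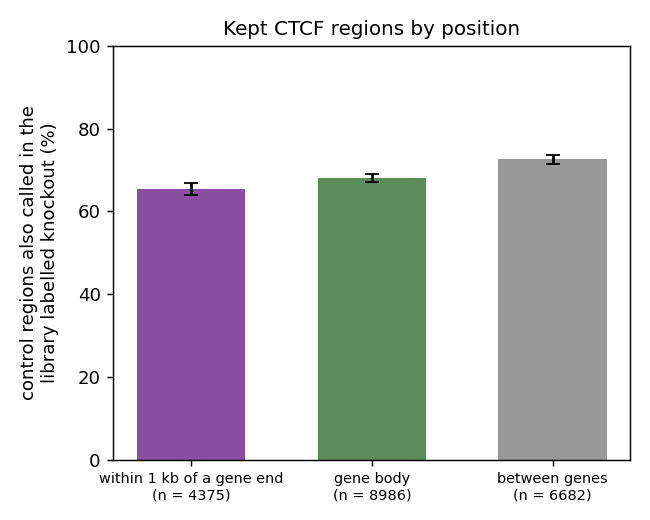
Percentage of control CTCF regions also called in the library labelled knockout (vertical axis, bars from 0) by position of the summit, with Wilson 95% intervals. The bars stand at 65.4% within 1 kb of a gene end, 68.1% in gene bodies and 72.7% between genes, and the order of the first and second bars turns with a stricter −log10 q or a window of 5 kb.

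The kept share was similar over the autosomes and lower on chromosome X. It lay between 65.8% and 72.1% over the 19 autosomes and was 69.1% over all of them. On X, 155 of 272 control regions were kept (57.0%, interval 51.0 to 62.7). X regions had a median recovered pileup of 12 reads against 15 on the autosomes, and other chromosomes at the same pileup gave an expected share of 58.3%. With a −log10 q of at least 5, 87 of 174 X regions were kept (interval 42.7 to 57.3%), against 60.5% expected at the same pileup and 71.8% on the autosomes. In the library labelled knockout 62 of 217 X regions (28.6%, interval 23.0 to 34.9) overlapped no control region, against 11.7% to 16.9% over the autosomes. X regions were weaker in this list too, with a median recovered pileup of 12 reads against 14 on the autosomes. This share was not matched on pileup. Chromosome Y held 58 control regions, of which 55 were kept, and 83 regions in the other list.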

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

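The minimum pileup of 15, the thinned comparison and the settings tried on the X chromosome were chosen after the data were examined; the others were planned. No paired analysis was possible because each genotype had 1 library. The motif alternatives were not run, since no sequence was used here. The numbers of regions stayed within 1.5 times under both stricter thresholds, and the labelled-knockout number divided by the control number was 0.857 with the −log10 q threshold and 0.858 with the fold threshold. It was 0.741 with a pileup of at least 15 and 0.996 when the control was also thinned by the ratio of the lowest backgrounds, against 0.805 as deposited. In the thinned comparison the labelled-knockout number was above the control mean at a pileup of at least 18, 20 and 40 (by 1.33%, 1.63% and 3.02%) and below it at the other limits. The share of control regions kept was 71.6% with a −log10 q of at least 5, 71.3% with a fold enrichment of at least 5, 59.8% with a reciprocal overlap of at least 50%, 65.2% with summits within 100 bp, 78.5% with lists of equal length and 96.7% in the strongest 25% of control regions, against 69.0%. The share of labelled-knockout regions with no control region was 16.2%, 16.8%, 25.7%, 19.004% and 21.0% under the first 5 of these, against 14.2%. Kept regions stayed stronger than lost ones under the 3 alternatives tried. The difference between gene ends and intergenic regions was -3.00 points with the −log10 q threshold, -3.34 with the fold threshold and -2.51 with a window of 5 kb, against -7.30; at the same control fold enrichment these were -5.83, -5.15 and -3.77, against -7.54. Gene ends were above gene bodies with the −log10 q threshold (71.1% and 69.98%) and the window of 5 kb (68.8% and 67.5%). The number of gene lists outside the central 95% of random lists was 1 with the −log10 q threshold, 2 with the fold threshold, 1 with reciprocal overlap, 1 with summits within 100 bp, 3 with a window of 2 kb and 2 with a window of 50 kb, against 0. The cause of these shifts was not tested. The cardiac transcription factors were outside under the fold threshold, summits within 100 bp and both other windows (percentiles 0.8, 0.4, 1.95 and 1.75), and the Hox clusters under the −log10 q threshold, reciprocal overlap and the window of 50 kb (0, 1.1 and 0.425). Fatty acid and energy metabolism was outside on the high side under the fold threshold (97.7). With the window of 2 kb, stress and fetal genes (1.88) and CTCF and cohesin (1.25) were outside on the low side. The Hox percentiles can be too extreme, because 29 Hox genes shared 21 control regions at the deposited threshold. Among single lists, position classes and the X chromosome, 92 values stayed within counting error and 17 moved. Those that stayed were mostly single lists, with wide error, and position classes mostly moved.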

Other observations

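The tests of depth, of signal at shared regions, of local background and the comparisons at gene ends were chosen after the results they concern had been seen; those on chromosome X at the deposited threshold and on counting noise with 12 reads were written before. The X chromosome at other settings was added later, and the limit of 9 reads was no part of the prediction. The regions with the highest −log10 p in both lists lay near pseudogenes on chromosome 8, with a local background above the lowest of their library. The highest in the control was on chromosome 8 (20122070 to 20122487), 14.03 kb from the pseudogene Gm21811, with a −log10 p of 148 and a local background of 3.69 reads. In the library labelled knockout it was a region 0.032 kb from 2610005L07Rik on the same chromosome (20424617 to 20425056), with 147. The kept share at gene ends minus that between genes was -5.34 points at the same control pileup (bootstrap 95% interval -6.81 to -3.84), and -7.72 points where the control background was under 1.1 (interval -10.3 to -5.12).

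The list labelled CTCF knockout was shorter than the control list. At a pileup of at least 15 its number of regions differed by -0.359% from that of the control thinned by the ratio of the lowest backgrounds, so a lower depth may account for the shorter list among regions of that strength. That ratio mixes read number with fragment length, and the lists give no depth itself. At lower pileups the thinned control held more regions, by a difference of -12.1% at a pileup of at least 8, where thinning does not repeat the peak calling. A lower signal at the regions called in both libraries stays open. The summed pileup ratio over 6747 of them was 1.03 of the ratio of lowest backgrounds, but a region had to be called in the library labelled knockout to enter it, so it decides nothing. Cells in which CTCF remained, an immunoprecipitation limited by the antibody and a wrong label were not tested and stay open, as does an effect of the genotype at single regions.

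Fewer control regions were kept on chromosome X than on the autosomes. Weaker control peaks on X may account for this at the deposited threshold, where the share expected at the same control pileup was 58.3% and the observed share 57.0% (interval 51.0 to 62.7). The expected share also lay inside the interval with a fold enrichment of at least 5 and under both other overlap rules. With a −log10 q of at least 5 it lay outside, at 60.5% against 87 of 174 regions (interval 42.7 to 57.3), so the explanation stays open. No biological explanation was tested, and the labels do not give the sex of the mice.

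Some strong control regions had no region in the library labelled knockout. Among 3883 control regions with a pileup of at least 20 and a background under 1.5, 111 were lost. Counting noise could give this number if a call needs 12 reads (mean 116, highest 143 over 100 simulations), as the prediction had set. If a call needs 9 reads the simulations gave fewer lost regions (mean 14.99, highest 25). They took the thinned observed control pileup as the true mean, which can understate losses among regions chosen for a high pileup. Of the 16128 labelled-knockout regions 4415 (27.4%) had fewer than 12 reads, so counting noise stays open. Of strong control regions with a background of at least 5, 78.0% were kept (interval 72.7 to 82.5) against 96.9% elsewhere (96.4 to 97.3). Their median fold enrichment was 2.94 against 10.97, so this comparison does not tell multi-copy sequence from low enrichment. They were kept more often than the weakest bin of control fold enrichment (32.5%), but that bin was not limited to a pileup of at least 20. It reached up to a fold enrichment of 4.49, so it also held regions of this group. That contrast therefore decides nothing either. Of the lost regions with a pileup of at least 20, 61 had a background of at least 5 and 178 a lower one. The 111 lost regions above were chosen for a background under 1.5. The limit of 5 thus places only the 61 among regions of high background, where multi-copy sequence stays open. At lost regions with a lower background multi-copy sequence was not tested and stays open too. The genotype stays open for all of the lost regions.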
